A study of Mus musculus with 4 samples.

How the data were processed

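Chromatin immunoprecipitation followed by sequencing was carried out on lineage-negative mouse bone marrow cells with antibodies against Ldb1, Tal1 and Gata2 and with control IgG, 1 library each. Per the labels' protocols, cells were crosslinked with formaldehyde, chromatin was sonicated and immunoprecipitated, and the DNA was end-repaired and sequenced on an Illumina Genome Analyzer. The deposited files list aligned tags, 1 line per tag, with chromosome, start, end and strand. They have no header and are not normalized, and repeated tags were kept. The genome build is mm8, per the submitters' processing notes; the aligner, its version and its filters are not given in the sources used here. The authors' files were not all made the same way. In the deposited Ldb1 and IgG files the score column is 0 throughout and each tag has a class of 0, 1 or 2 mismatches, whereas in the deposited Tal1 and Gata2 files each tag has a match descriptor and a score from 4 to 119 (Tal1) or from 4 to 53 (Gata2). The scores were not used. Tags were 36 bp long for Tal1 and 25 bp for the others. Tags without a mismatch made up 74.9% for Ldb1, 90.9% for Tal1, 95.2% for Gata2 and 63.5% for IgG. Longer tags can be placed in more repeats, and the mapping rules may have differed between the files, so a factor and IgG are not equally mappable everywhere. The factor libraries were therefore also compared after leaving out places with few IgG tags.

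Tags were counted once per position and strand, since 32.9% of Ldb1, 18.3% of Tal1, 14.1% of Gata2 and 29.9% of IgG tags repeated a position. Mitochondrial tags were left out. The fragment length was the distance between strands, from 60 bp upwards, at which tag pairs smoothed over 15 bp were most frequent on the autosomes outside 10 kb bins of over 5 times the mean, and tags were moved towards the fragment centre (by 56 bp for Ldb1, 54 bp for Tal1, 53 bp for Gata2, 54 bp for IgG). Tags were counted in windows of 400 bp every 100 bp. The expected count was the largest of the factor's genome mean and the IgG count in 1, 5 and 10 kb around the window, scaled by the ratio of total tags. The genome mean was taken over the 2397.1 Mb of 1 kb bins with a tag in any library. Windows with at least 3 tags were tested with a one-sided Poisson test, with Benjamini-Hochberg adjustment over all windows with a tag. Windows at a false discovery rate of at most 0.01 and at least 4-fold over expectation were kept, and those that overlapped or touched were joined into regions. The fold of a region is that of its best window and is taken over an expectation that is never 0. The summit is the position with most tags within 50 bp. Background was measured by exchanging factor and IgG.

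Regions were called shared when they overlapped by at least 1 bp. Chance overlap came from 1000 circular shifts of the second list along each chromosome. Intervals are 95% exact (Clopper-Pearson, or conditional binomial for ratios of counts); they cover counting error only, since PCR copies and neighbouring windows are not independent. Tag density was compared with flanks 3 to 5 kb from the centre. The centre of a merged region is the summit of the factor with the highest fold there. For the regions of a given factor it is the summit of that factor. The calling step was tested on simulated libraries with the depth of each factor and planted sites of known fold. At 20-fold, 91.8% of 1055 planted sites were recovered at the Ldb1 depth, 99.5% of 1050 at the Tal1 depth and 98.7% of 1021 at the Gata2 depth. At 10-fold these shares were 25.0% of 973, 77.0% of 1001 and 54.2% of 957. At 5-fold they were 1.49% of 1006, 8.85% of 983 and 3.31% of 1056. Between 0.810% and 1.45% of calls lay away from a planted site. Within the simulations, recovery was lowest for weak sites and at the Ldb1 depth. The simulations gave 1234 calls at the Ldb1 depth, 1922 at the Tal1 depth and 1584 at the Gata2 depth. These are far fewer than the regions of the real lists, so the false discovery cut was stricter. Planted sites were also spread over more than 400 bp, so their fold in a window was below the fold named. The shares can therefore understate recovery in the real libraries.

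Groups, the tests of the planned comparisons, their alternatives and the gene lists were fixed before the data were examined. The alternatives with split IgG tags, with tags without a mismatch and with a minimum of IgG tags, and the tests of clusters and of chromosome X, were chosen afterwards. The flank distance was set after that but before any density was computed. The comparison of regions with 1 partner and the comparisons on random subsets of tags were chosen after overlaps and first distances had been seen, and the latter were redone once so that each pair used the same 800 bp around the centre. The rule for named regions took the 10 regions of all 3 factors with the largest lowest-of-3 fold, the 3 regions of each factor with most tags in the best 400 bp window, and for each factor up to 3 regions of at least 20 tags in that window and largest fold with no region of another factor within 1000 bp. Regions with more than 5 times the mean IgG count were not named, which removed 75 regions of all 3 factors. The planned tests of gene lists, of location relative to genes and of sequence motifs were not run, because no annotation or sequence of mm8 was used here and coordinates were not converted between builds. Alternatives covered repeated tags, thresholds, window size, IgG scaling, no IgG, equal tag numbers (1 random draw of 3614604 tags per library), tag shift, the definition of overlap, the chance model, signal width and the order by which regions were ranked. Analyses used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.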

Results

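Chromatin from freshly isolated mouse bone marrow cells, depleted of lineage-positive cells with magnetic beads, was immunoprecipitated with 4 antibodies and sequenced. The lineage-negative fraction is enriched for haematopoietic stem and progenitor cells. The antibodies recognised Ldb1 (LIM domain binding protein 1, a cofactor that does not bind DNA itself and joins DNA-bound proteins into complexes), Tal1 (also called Scl, a basic helix-loop-helix transcription factor of blood cells), Gata2 (a zinc finger transcription factor of stem and progenitor cells) and, as the control, non-specific IgG. The stated purpose of the series was to learn what Ldb1 does in keeping haematopoietic stem cells. Each antibody had 1 library, so no comparison here has a biological replicate. Every interval and test below covers counting error between these libraries only, and not variation between animals or immunoprecipitations. The Ldb1 file held 6042990 aligned tags, the Tal1 file 11134890, the Gata2 file 7053702 and the IgG file 5156509. Counted once per position and strand, these were 4056964, 9091843, 6059558 and 3615239 tags. Tags on the forward and reverse strands were displaced from each other by 111 bp for Ldb1, 107 bp for Tal1 and 106 bp for Gata2. Near that distance, tag pairs were 3.71 times as frequent as near 400 bp for Ldb1, 2.65 times for Tal1 and 1.98 times for Gata2, against 1.39 times for IgG, whose pairs were most frequent at 25 bp (1.79 times). All positions are in the mouse genome build mm8. Genes, exons and introns are not assigned to positions, because no annotation of mm8 was used here.

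The first comparison set each factor against IgG and asked where in the genome it was bound. All 3 factors had many sites with far more tags than IgG. Tal1 had 36677 occupied regions, Gata2 22174 and Ldb1 13744. These took in 12.4% of all Tal1 tags, 6.35% of Gata2 tags and 5.79% of Ldb1 tags, while the same regions held 1.08%, 0.652% and 0.391% of the IgG tags. The regions were short, with a median width of 600 bp for Ldb1 and Gata2 and 700 bp for Tal1. The median enrichment over the local expectation was 11.7-fold for Ldb1, 8.90-fold for Gata2 and 7.91-fold for Tal1. Regions were called by a one-sided Poisson test at a false discovery rate of 0.01. Exchanging the factor and IgG gave 27 regions for Ldb1, 242 for Tal1 and 188 for Gata2, which is 0.196%, 0.660% and 0.848% of the real calls. IgG had fewer tags than each factor, so the exchange had less power and these shares can understate the background.

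These orders depended on depth and on repeated tags. With every library thinned to the tag number of IgG, Tal1 had 21770 regions, Gata2 15712 and Ldb1 14301, so the Tal1 to Ldb1 ratio was 1.52 in place of 2.67. The median enrichment was then highest for Tal1 (12.5-fold, against 11.6-fold for Ldb1 and 11.2-fold for Gata2). Tal1 regions held 9.99% of the Tal1 tags, Ldb1 regions 5.91% of the Ldb1 tags and Gata2 regions 5.22% of the Gata2 tags. With repeated tags counted as deposited, Ldb1 had the most regions (83366), ahead of Tal1 (56236) and Gata2 (35117). Of these Ldb1 regions, 69959 were not called when positions counted once, and their best windows held a median of 8 tags on 4 positions. The region counts still rose between 75 and 100% of the tags of each library. They did not follow depth evenly, since Ldb1 had more regions when thinned (14301, with at least 6 tags in the best window) than with all its tags (13744, with at least 7).

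**Figure D1:**
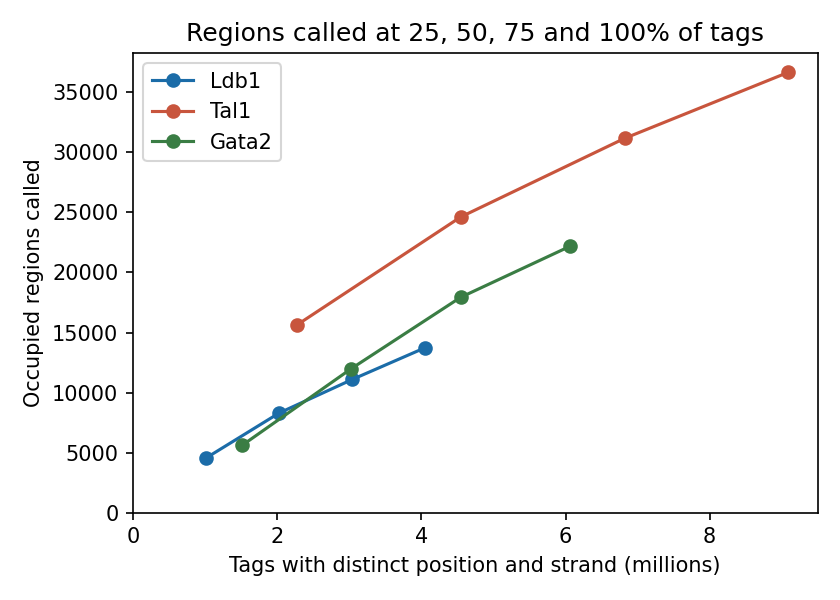
Occupied regions called (vertical axis) against the number of tags with a distinct position and strand (horizontal axis), at 25, 50, 75 and 100% of the tags of each library. Ldb1 went from 4549 to 13744 regions, Gata2 from 5604 to 22174 and Tal1 from 15624 to 36677, and all 3 lines were still rising at full depth.

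The second comparison asked whether Ldb1, Tal1 and Gata2 occupied the same places. Most Ldb1 regions were also Tal1 regions: 11045 of 13744 overlapped, or 80.4% (95% exact interval 79.7 to 81.0), where circular shifts of the Tal1 list along each chromosome gave a mean of 2.13%. Gata2 regions overlapped 6799 Ldb1 regions, or 49.5% (48.6 to 50.3), against 1.22% by chance. Of the Gata2 regions, 59.3% (58.6 to 59.9) overlapped Tal1 and 30.6% (30.01 to 31.2) overlapped Ldb1. Of the Tal1 regions, 35.4% (34.9 to 35.9) overlapped Gata2 and 29.6% (29.1 to 30.04) overlapped Ldb1. Each of these 6 shares was above every one of 1000 shifts in a one-sided permutation test (p = 0.001, the smallest that 1000 shifts can give; the 6 adjusted values equal the raw ones). The same shares lay 27.5 to 40.7 times above the mean of the shifts. At equal tag numbers the Ldb1 share in Tal1 was 62.4% (61.6 to 63.2) and the Ldb1 share in Gata2 was 35.96% (35.2 to 36.8). For Tal1 regions the order turned, with 40.8% in Ldb1 (40.2 to 41.5) and 31.8% in Gata2 (31.1 to 32.4). With repeated tags kept, 24.2% of the Ldb1 regions were in Tal1 and 15.2% in Gata2, still above chance.

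By number of regions, Ldb1 was found with Tal1 more often than with Gata2, and the Tal1 list was the longer. Relative to chance the order was the other way with all tags (37.6 times chance for Tal1 and 40.7 times for Gata2), and at equal tag numbers it was 51.1 times for Tal1 and 43.5 times for Gata2. Among the 5042 Ldb1 regions that had only 1 of the other factors, that factor was Tal1 in 4644 and Gata2 in 398, so Tal1 accounted for 92.1% (91.3 to 92.8). At equal tag numbers Tal1 accounted for 83.0% (82.0 to 83.9) of 5737 such regions. Equal tag numbers did not make the lists equal: Tal1 then had 21770 regions with 9.99% of its tags, and Gata2 15712 with 5.22%. A preference of Ldb1 for Tal1 can thus not be told apart from stronger enrichment in the Tal1 library. Gata2 regions with 1 partner had Tal1 rather than Ldb1 in 6742 of 7124 cases, and Ldb1 in 5.36% (4.85 to 5.91), which became 26.8% (25.4 to 28.2) at equal tag numbers. For Tal1 regions with 1 partner the direction depended on depth. Ldb1 was the partner in 40.4% (39.5 to 41.3) of 11055 regions with all tags, and in 63.2% (62.1 to 64.3) of 7456 regions at equal tag numbers.

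The 3 lists were called against the same IgG library, and part of any overlap can come from a shared control. In bins of 10 kb, independent lists of the same sizes would share 1289 of 251167 bins for Ldb1 and Tal1, and 10091 were shared. The corresponding values were 882 and 7105 bins for Ldb1 and Gata2, and 2008 and 12792 bins for Tal1 and Gata2. The shared bins were thus 7.83, 8.06 and 6.37 times those of independent lists, in that order of pairs. The bins hold the same calls against the same IgG and were all treated alike. They therefore do not test a shared control. IgG was also called against its own genome mean, at the same false discovery rate of 0.01 and at least 4-fold. The 1114 regions so called overlapped 30 Ldb1, 12 Tal1 and 20 Gata2 regions, but the calling rule itself removes places dense in IgG tags.

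**Figure D2:**
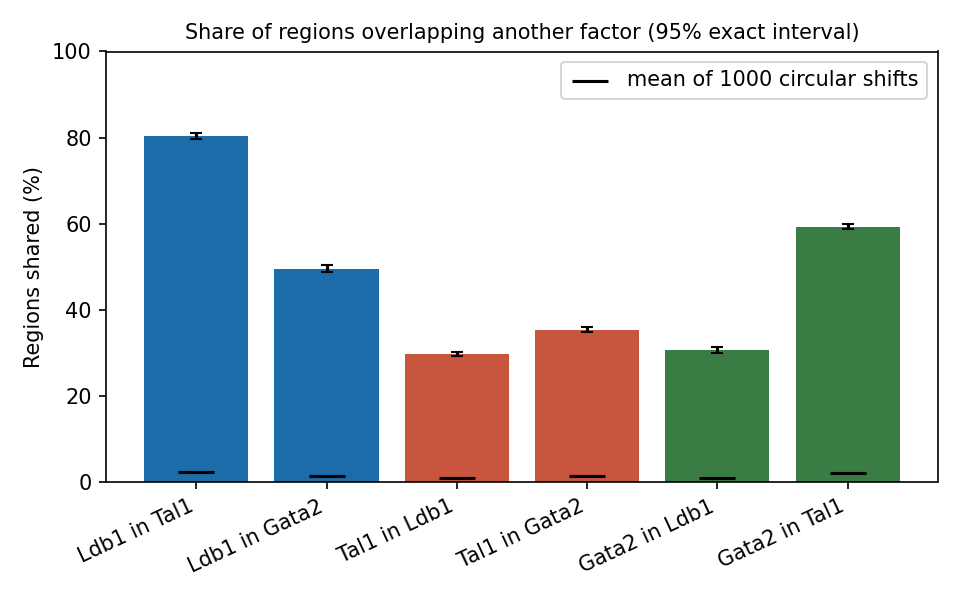
Share of the regions of each factor, in percent, that overlapped a region of another factor by at least 1 bp. Bars give the share with all tags counted once per position and strand, error bars the 95% exact binomial interval, and black dashes the mean of 1000 circular shifts. The share of Ldb1 in Tal1 was highest at 80.4%, and every dash lay at or below 2.13%.

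The design of 3 antibodies also asked which regions held all 3 factors. Merging the lists gave 47736 regions, of which 6369 (13.3%) had all 3 factors, 11181 had 2 and 30186 had 1. Circular shifts gave a mean of 6.04 regions with all 3 factors and at most 24 (one-sided permutation p = 0.001, the smallest possible). Regions with Ldb1 and Tal1 but no Gata2 call numbered 4411, those with Tal1 and Gata2 but no Ldb1 call 6411, and those with Ldb1 and Gata2 but no Tal1 call only 359. Regions of 1 factor numbered 19241 for Tal1, 8644 for Gata2 and 2301 for Ldb1. At equal tag numbers 4193 regions had all 3 factors, and Ldb1 regions with neither partner were 30.8% of the list in place of 16.7%.

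Pooled over regions, Ldb1 and Tal1 tags were densest in regions called for all 3 factors. Within 400 bp around the centre of these 6369 regions, the Ldb1 tag density was 15.3 times that of the flanks (15.2 to 15.5), Tal1 14.7 times (14.6 to 14.8) and Gata2 9.50 times (9.41 to 9.58), while IgG was at 1.17 times (1.13 to 1.21). Regions with Ldb1 and Tal1 alone had 11.7-fold Ldb1 (11.6 to 11.9) and 12.6-fold Tal1 density (12.5 to 12.7). The typical Tal1 region went the other way, with a median enrichment of 15.2-fold in regions of Ldb1 and Tal1 alone and 14.4-fold in regions of all 3. Where Tal1 had no partner its density was 5.39 times that of the flanks (5.36 to 5.41), and where Ldb1 had none its density was 7.54 times (7.38 to 7.69). Gata2 changed less between classes, from 6.65-fold (6.41 to 6.90) with Ldb1 alone to 9.50-fold with both others. In regions of several factors, tags were counted around the summit of the factor with the highest fold. A factor with its summit elsewhere was undercounted. The 359 regions with Ldb1 and Gata2 alone had the highest IgG density, 2.28 times that of the flanks (2.07 to 2.50).

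Tags of a factor were also enriched at regions where it had not been called. At the 6411 regions of Tal1 and Gata2 alone, Ldb1 density was 3.17 times that of the flanks (3.12 to 3.22). At the 4411 regions of Ldb1 and Tal1 alone, Gata2 density was 2.57 times (2.53 to 2.61). At regions of Tal1 alone, Ldb1 stood at 2.22 times (2.20 to 2.24) and Gata2 at 2.05 times (2.03 to 2.07), with IgG at 0.994 times (0.975 to 1.01). Pooled over all Ldb1 regions, Tal1 tags were 20.5-fold (20.1 to 20.97) and Gata2 tags 8.29-fold (8.12 to 8.47) above IgG. Ldb1 tags were 9.15-fold (9.02 to 9.28) above IgG over all Tal1 regions and 8.11-fold (7.98 to 8.25) over all Gata2 regions. Regions were selected for tags of the called factors and for few IgG tags, which raises the densities of called factors and the folds over IgG and lowers the densities of factors that were not called.

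**Figure D3:**
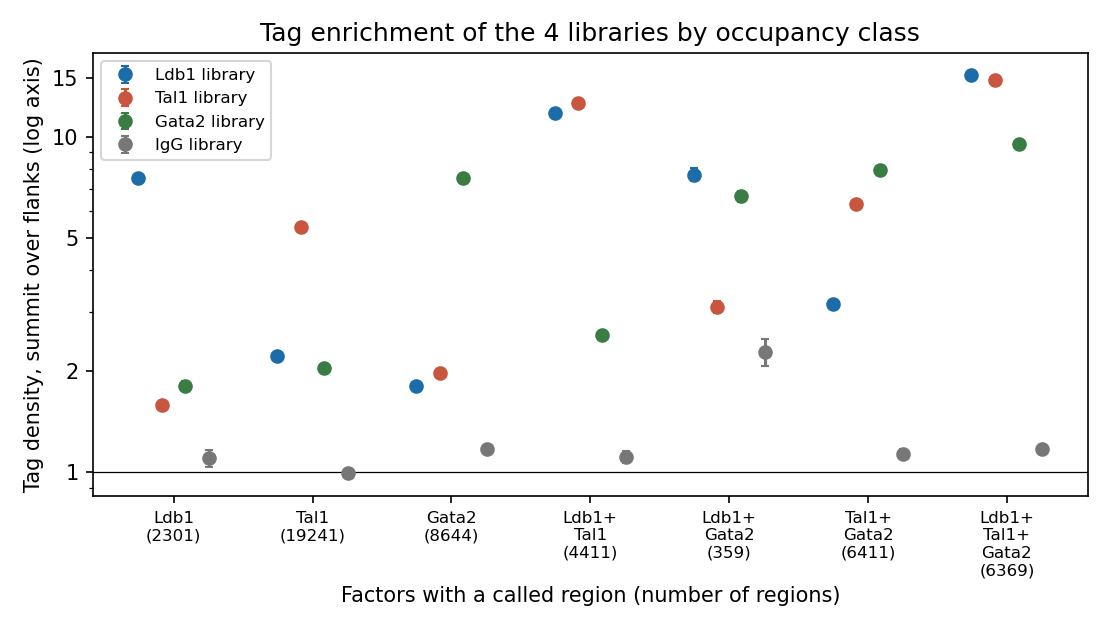
Tag density within 400 bp around the region centre divided by the density 3 to 5 kb away (log axis), for the 4 libraries in the 7 classes of regions, with 95% exact intervals from pooled counts. Ldb1 and Tal1 were highest in the 6369 regions of all 3 factors (15.3 and 14.7), and IgG stayed between 0.994 and 1.18 except in the class of Ldb1 and Gata2 alone (2.28).

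The strongest regions were shared more than the weakest. In the strongest 25% of Ldb1 regions by fold, 62.4% (60.8 to 64.1) had both Tal1 and Gata2, against 37.0% (35.3 to 38.6) in the weakest 25%. Only 13 of the 3436 strongest Ldb1 regions had neither partner, or 0.378% (0.202 to 0.646), against 26.3% (24.9 to 27.8) of the weakest. The rise by fold was not even for Ldb1: in the next 25% above the weakest, 35.8% (34.2 to 37.5) had both partners and 30.03% (28.5 to 31.6) had neither. Ranked by tag count, 24.7% of the weakest and 62.1% of the strongest 25% of Ldb1 regions had both partners. Near the smallest called count of 7 tags, fold also depends on the local expectation. The uneven rise can therefore not be read as a feature of binding. The share of Tal1 regions with both partners was 38.4% (37.4 to 39.4) in the strongest 25% and 4.94% (4.51 to 5.40) in the weakest. For Gata2 these shares were 47.3% (46.0 to 48.6) and 18.9% (17.9 to 19.9). Among the strongest 25% of Tal1 and Gata2 regions, 22.2% (21.3 to 23.0) and 22.4% (21.3 to 23.5) had no partner. These shares were not computed at equal tag numbers.

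**Figure D4:**
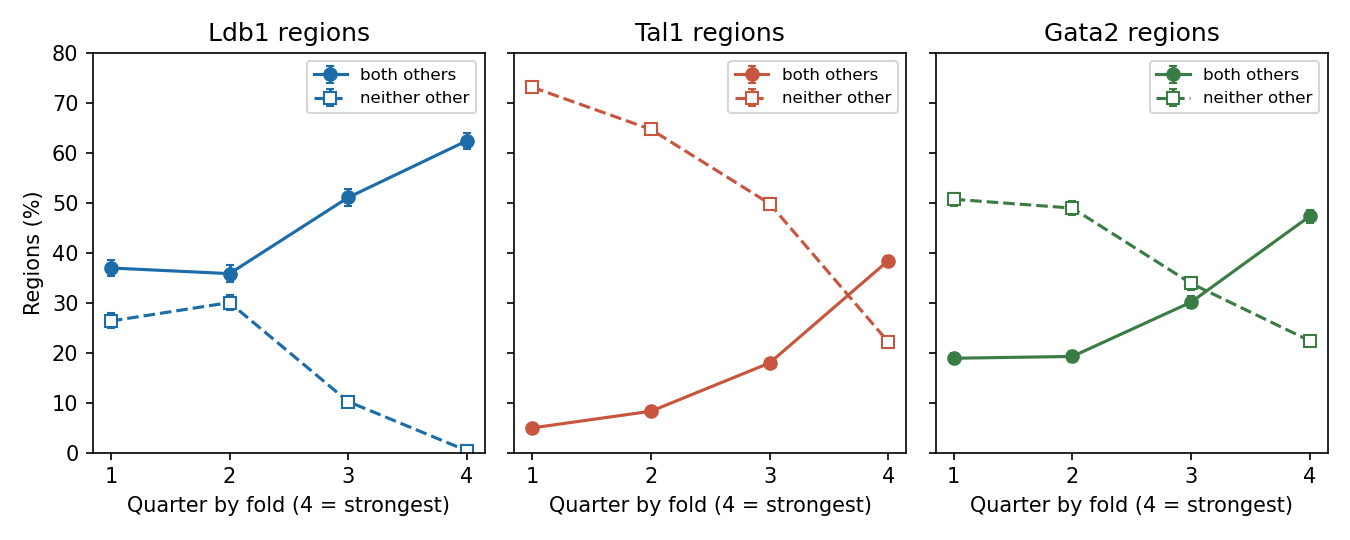
Percent of Ldb1, Tal1 and Gata2 regions that overlapped regions of both other factors (filled circles) or of neither (open squares), in 4 equal parts of each list ordered by fold enrichment, with 95% exact intervals. The share with neither partner was 0.378% in the strongest 25% of Ldb1 regions but 22.2% for Tal1 and 22.4% for Gata2.

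Within the 6369 regions of all 3 factors, the Ldb1 and Tal1 tag numbers around a common centre varied together, while those of Gata2 followed them less closely. The correlation of log2 tag numbers was 0.713 for Ldb1 and Tal1 (Spearman's rho 0.644), 0.266 for Ldb1 and Gata2 (rho 0.208) and 0.330 for Tal1 and Gata2 (rho 0.274). These are correlations across regions, which are not independent replicates, so no p-value is given. The common centre was the summit of the factor with the highest fold. A factor with its summit elsewhere was undercounted, which can lower its correlations, also between subsets of its own tags. The median enrichment in these regions was lowest for Gata2 (10.9-fold, against 13.3-fold for Ldb1 and 14.4-fold for Tal1). How much this lowered the Gata2 values was not tested. On random subsets of 50% of the tags, Ldb1 and Tal1 correlated at 0.650 and Ldb1 and Gata2 at 0.227. The 2 subsets of the same library correlated at 0.712 for Ldb1, 0.895 for Tal1 and 0.611 for Gata2. The values with IgG over all tags were 0.0183 for Ldb1, 0.00637 for Tal1 and 0.105 for Gata2.

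Summit distances between the 3 factors in these regions were measured only within a fixed stretch around the region centre. Summits outside that stretch could not appear, so short distances were partly built in, and no chance distance is given. In 4206 Ldb1 regions, a called Tal1 summit and a called Gata2 summit each lay within 200 bp of the Ldb1 summit. By overlap of at least 1 bp, 6401 Ldb1 regions had both partners. The Tal1 and Gata2 summits were not required to lie within 200 bp of each other. Measured on random subsets of 50% of the tags, the median distance was 53 bp between Ldb1 and Tal1, 75 bp between Ldb1 and Gata2 and 66 bp between Tal1 and Gata2. The 2 subsets of a library placed their own summits a median of 54 bp apart for Ldb1, 37 bp for Tal1 and 65 bp for Gata2. For Ldb1 and Tal1, 84.4% of distances were within 200 bp, against 86.3% for the Ldb1 subsets and 86.6% for the Tal1 subsets. The median between Ldb1 and Tal1 was near that of the Ldb1 subsets but above that of the Tal1 subsets. These values do not decide whether Ldb1 and Tal1 summits are separated.

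The regions of all 3 factors with the largest lowest-of-3 enrichment were named by a fixed rule. The first lay on chromosome 1 from 182686801 to 182688300, with 208-fold Ldb1, 116-fold Tal1 and 108-fold Gata2 enrichment. It held 229 Ldb1, 284 Tal1 and 174 Gata2 tags within 400 bp, and 1 IgG tag. The second, on chromosome 14 from 53659401 to 53661300, had 179-fold Ldb1, 196-fold Tal1 and 104-fold Gata2 enrichment. The third lay on chromosome 18 from 61883801 to 61885200, with enrichments of 84.2-fold for Ldb1, 111-fold for Tal1 and 89.0-fold for Gata2. On chromosome 16 there were regions from 92688901 to 92691200 and from 93034801 to 93036900, whose lowest enrichments, for Gata2, were 80.1-fold and 72.2-fold. IgG had 0 tags in both. An IgG count of 0 allows up to 3 tags. The remaining 5 lay on chromosome 5 from 139986001 to 139987200, chromosome 18 from 50153001 to 50154600, chromosome 1 from 89792401 to 89793400, chromosome 7 from 15452701 to 15455300 and chromosome 11 from 95171901 to 95173800. Their lowest enrichments were between 72.2-fold and 78.3-fold. IgG had 0 or 1 tag at each of the 10 regions.

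By tags in the best 400 bp window, the same region came first for Ldb1 and for Tal1, on chromosome 16 from 32428301 to 32430800, with 276-fold Ldb1, 194-fold Tal1 and 64.9-fold Gata2 enrichment. A region on chromosome 8 from 87590901 to 87592300 was the next by Ldb1 (226 tags in the best window, against 224 for the region of chromosome 1 from 182686801), with 126-fold Ldb1, 64.4-fold Tal1 and 59.7-fold Gata2 enrichment. The second by Tal1, on chromosome 16 from 17551401 to 17552900, had 183-fold Tal1 and 151-fold Ldb1 but 10.4-fold Gata2 enrichment, with 340 Tal1, 126 Ldb1 and 12 Gata2 tags. By Gata2, a region of chromosome 1 from 24565501 to 24570800 came first, with 255-fold Gata2, 179-fold Tal1 and 52.3-fold Ldb1 enrichment. It was 5300 bp long. The factor files, unlike the IgG file, list no mitochondrial tags, and whether this region is a nuclear copy of mitochondrial sequence was not examined, so its folds cannot be taken as binding. A region of chromosome 2 from 22439901 to 22442500 followed, with 93.5-fold Gata2, 79.5-fold Tal1 and 20.05-fold Ldb1 enrichment.

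Some strong regions were called for 1 factor, with no called region of another within 1000 bp. The other factors are not thereby absent, since the smallest called region had 7 Ldb1, 9 Tal1 or 8 Gata2 tags in its best window and some counts of the other factors lay just under these. Tal1 alone reached 51.4-fold on chromosome 10 from 80318201 to 80319000, where there were 78 Tal1 tags against 5 Ldb1, 6 Gata2 and 0 IgG tags. Values were similar on chromosome 17 from 27310801 to 27311800 (50.8-fold) and chromosome 1 from 135017901 to 135018800 (50.1-fold). Gata2 alone reached 67.5-fold on chromosome 17 from 35631401 to 35632300, where there were 78 Gata2 tags against 0 Ldb1, 7 Tal1 and 1 IgG tag. It reached 63.3-fold on chromosome 2 from 104326201 to 104327000 and 50.4-fold on chromosome 15 from 98333401 to 98334800. Ldb1 alone had only 1 region with at least 20 tags that met the rule, on chromosome 16 from 6011101 to 6011900. It had 26 Ldb1 tags at 26.0-fold enrichment, against 1 Tal1, 0 Gata2 and 1 IgG tag.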

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

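The following signals lie in tags that the comparisons did not use, because positions were counted once and mitochondrial tags were left out. They were found by listing the 3 positions with most tags in each library and keeping those with over 400 tags and 0 in the other libraries, a choice made after the tags had been seen. The IgG library held 112803 tags at position 60832754 of chromosome 16, 2.19% of the library, and the other libraries had 0 there. It held another 25686 tags at position 107783674 of chromosome 3 and 877 at position 87277478 of chromosome 12, again with 0 in the other libraries. The Ldb1 library held 1326 tags at position 166133140 of chromosome 2 and 486 at position 87085805 of chromosome 6, where IgG, Tal1 and Gata2 had 0. The Tal1 library held 2012 and 1843 tags at neighbouring positions 39187654 and 39187655 of chromosome 14 and 1934 tags at position 3016105 of chromosome 9. No other library had a tag at those exact positions, although each had at least 258 tags within 500 bp. The IgG file was the only file with mitochondrial tags, 935 in all. No explanation of these signals was tested.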

How the results depend on the processing

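The IgG split, tags without a mismatch and the minimum of IgG tags were chosen after seeing the data, and moved no count by over 1.5 times. Values were compared by kind: overlap shares by their side of chance, counts by a change of 1.5 times, and enrichments and shares by strength by their 95% interval. Of 131 values recomputed under alternatives, 89 stayed within these bounds, 42 did not and none of them reversed. The 89 include the values under windows matched on IgG, where only chance was recomputed and the count of 6369 could not change. Orders between factors did turn. With repeated tags kept, the order of the 3 region numbers turned. At equal tag numbers, orders given above turned, among them those of the partners of Tal1 regions and of the median enrichments. The 3 overlap shares recomputed (Ldb1 in Tal1, Ldb1 in Gata2 and Gata2 in Tal1) stayed above chance under every alternative run (permutation p = 0.01, the smallest that 100 shifts can give). The share of Ldb1 regions in Tal1 ranged from 24.2% with repeated tags kept to 91.2% at a false discovery rate of 0.0001, and that in Gata2 from 15.2% with repeated tags kept to 59.6% with 1000 bp windows. With repeated tags kept there were 83366 Ldb1, 56236 Tal1 and 35117 Gata2 regions and 10604 of all 3. Of those Ldb1 regions, 69959 were not called when positions counted once, and their best windows held a median of 8 tags on 4 positions. A false discovery rate of 0.0001 gave 7598 Ldb1, 13037 Gata2 and 3404 regions of all 3; at least 8-fold gave 18154 Tal1, 13569 Gata2 and 3875 of all 3. Windows of 1000 bp gave 22836 Tal1 regions. Without IgG there were 26690 Ldb1, 40498 Gata2 and 10776 of all 3. Equal tag numbers gave 21770 Tal1 regions and 4193 of all 3. With summits within 200 bp, 4206 Ldb1 regions had both partners. Ranked by tag count, the weakest 25% shared with both others were 24.7% for Ldb1, 2.99% for Tal1 and 14.4% for Gata2. With summits within 200 bp, the weakest and strongest 25% gave 21.2% and 49.6% for Ldb1, 2.41% and 29.9% for Tal1, and 11.1% and 34.2% for Gata2. Pooled enrichments over IgG left their intervals under each alternative and stayed above 1. In the order Tal1 at Ldb1 regions, Gata2 at Ldb1 regions, Ldb1 at Tal1 regions and Ldb1 at Gata2 regions, they were 24.6, 8.88, 10.5 and 9.32 with repeated tags kept, and 11.5, 5.65, 5.36 and 5.29 over 1000 bp. They were 24.6, 9.17, 9.90 and 8.78 with IgG scaled on background, and 28.9, 10.1, 11.3 and 10.1 at a false discovery rate of 0.0001. The cause of these changes was not tested. No replicate could be left out and no paired analysis was possible because each antibody had 1 library. Tests needing mm8 genes or sequence were not run, nor were their alternatives.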

Other observations

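The tests of clusters and of chromosome X, the interval on the ratio at equal tag numbers and the comparison of matched windows with unmatched shifts were chosen after results had been seen, as were the alternatives with split IgG tags and with a minimum of IgG tags. Regions of all 3 factors were gathered in clusters. Joining those at most 25 kb apart gave 54 clusters of at least 5 regions, which held 313 of the 6369 regions, or 4.91%. Random draws of as many regions per chromosome from all 47736 regions gave a mean of 96.5 and at most 156 in 100 draws (one-sided permutation p = 0.01, the smallest possible). The most populous cluster held 11 regions in 55.7 kb of chromosome 8, from 125160162 to 125215831, although a random draw also reached a cluster of 14. The next held 9 regions in 80.1 kb of chromosome 8, from 125542374 to 125622464. Clusters of 8 lay on chromosome 10 from 79436383 to 79520175 and on chromosome 17 from 35431117 to 35487872 and from 84022092 to 84097088.

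Chromosome 11 had the most regions per Mb for each factor (10.05 for Ldb1, 26.3 for Tal1 and 16.0 for Gata2), and among the larger chromosomes X had the fewest (1.31, 3.90 and 1.996). Chromosome Y, with 0.797 Mb covered, had 0, 2 and 0 regions. The X values were 22.9%, 25.5% and 21.6% of the genome mean, and 33.5%, 28.5% and 31.2% when regions were called without IgG. X held 5.90% of IgG tags, against 4.69% for Ldb1, 4.29% for Tal1 and 4.51% for Gata2. The region of chromosome 1 from 24565501 to 24570800 was 5300 bp long, with 33 Ldb1, 210 Tal1, 219 Gata2 and 0 IgG tags around its centre. Only the IgG file lists mitochondrial tags (935), and whether this region is a nuclear copy of mitochondrial sequence was not tested.

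The predictions for the 3 patterns below were set after the first region counts and overlaps were known, but before the values that test them. Tal1 had 2.67 times as many regions as Ldb1. A difference in reach of 36 bp and 25 bp tags is argued against as the whole cause, since the ratio was 2.67 also where IgG had at least 7.54 tags in 10 kb, although shorter repeats were not tested. Depth accounts for part of it: with equal tag numbers, in 1 random draw, the ratio was 1.52 (1.49 to 1.55), and its place above the preset limit of 1.5 cannot be told apart from counting error. The limit was set with no interval. If depth were the whole cause, equal tag numbers should bring the ratio near 1, and the interval lies above 1. This argues against depth as the whole cause for tags counted once, within counting error of 1 draw. Repeated tags remain open (ratio 0.675 when kept). That ratio counts repeats as separate tags. With repeats kept, 69959 of the 83366 Ldb1 regions were ones not called when positions counted once. Their best windows held a median of 8 tags on 4 positions. A wider distribution of Tal1 on chromatin and a difference between antibodies were not tested and also remain open.

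The 3 factors shared regions far beyond chance. A shared control is argued against as the whole cause. When IgG tags were split into 3 separate parts, 78.1% of Ldb1 regions still overlapped Tal1. The parts come from 1 library, so the split removes shared counting error but not a bias of that library. Called without IgG, 61.2% of Ldb1 regions overlapped Tal1, against 2.69% by chance. Places dense in tags of any kind stay open: windows matched on IgG tags overlapped 2.18% of Ldb1 regions, under the preset limit of 10%, but unmatched shifts gave 2.13%, so the matching changed nothing and tested nothing. Open chromatin that any antibody recovers could also contribute: at regions called in all 3 libraries without IgG, the IgG excess over flanks was 19.9% of the lowest factor excess, between the preset limits of 10% and 50%. Binding of the factors in a shared complex is among the open explanations and was not tested. The libraries came from separate immunoprecipitations of many cells, so overlap cannot show whether the factors were bound in the same cells.

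Of the Ldb1 regions, 2301 (16.7%) had no Tal1 or Gata2 region, and 30.8% had none at equal tag numbers. Tags piled wholly on 1 strand over several positions are argued against. Of these regions, 0.522% (0.270 to 0.909) had over 90% of their tags on 1 strand. The test cannot speak to pile-ups at a single position, because tags were counted once per position and strand. It was also coarse. The best window held a median of 7 tags, and 1 tag on the other strand keeps such a window under 90%. Pooled over the 2301 regions, Tal1 tags were 1.59 times those of the flanks (1.55 to 1.63) and Gata2 tags 1.81 times (1.76 to 1.87), with IgG at 1.10 times (1.04 to 1.17). Both values are consistent with the hypothesis that some of these regions may hold Tal1 or Gata2 below the threshold; which regions do cannot be read from pooled tags. Ldb1 binding with other partners was not tested.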
